A study of Homo sapiens with 30 samples.

How the data were processed

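Expression was measured on 30 one-colour arrays hybridised with biotin-labelled material made from total RNA, per the labels. All RNA came from Huh7.5, an established human hepatocellular carcinoma line. The arrays fall into 4 groups by line and treatment: 8 wild-type control arrays, 7 wild-type arrays with interferon alpha, 8 control arrays of the line over-expressing IRF9 and 7 arrays of that line with interferon alpha. Control arrays were taken at 0, 1, 2, 3, 4, 8, 12 and 24 h and stimulated arrays at 1 to 24 h, with 1 array for each combination of line, treatment and time. Cells had been starved for 3 h and then received 500 U/mL interferon alpha or none, per the labels' protocols. Every group was taken from the labels.

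The deposited values are log2 expression values of 33297 transcript clusters, made by the authors with oligo, per the submitters' processing notes. The steps run in oligo and its version are not given in the sources used here, and neither are scan dates or hybridisation batches. The deposited log2 values lay between 1.2333 and 14.0709, none was missing, and the array medians lay between 5.50 and 5.64, so the values were used without further normalization. The number of arrays limits the precision of every value. No count of molecules or reads stands behind an array value.

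Transcript clusters were named from the platform annotation used here. It listed 21214 clusters, of which 19460 carried a single gene symbol and 1754 carried several, while 12083 clusters were not listed and stay unnamed. Of the single-symbol clusters, 19429 had a gene number found in the RefSeq gene table, and 0 symbols needed an update. Clusters with a single symbol were tested, with the cluster of highest mean standing for each of the 769 genes that had more than 1, which left 18417 genes. Values of 557 rows repeated those of another row. No genome was used, so no coordinates are given. The 13837 clusters with several symbols or none are not named here and were tested only for the interferon response of each line.

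All tests were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), with Benjamini-Hochberg adjustment over the 18417 genes and a threshold of 0.05. Where no gene differs, a share of 0.05 of the genes falls under an unadjusted p of 0.05 by chance. Tables and figures were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The response to interferon alpha was the mean difference between stimulated and control arrays of the same line and time, fitted per line on 28 arrays with a block for each line and time. The difference between the lines' responses was fitted with terms for the shared response at each time, over the whole course and apart for 1 to 4 h and 8 to 24 h. The response at each time point was the mean over both lines. The lines were compared on the control arrays and on the stimulated arrays with time as a block. Change with time was tested on the 16 control arrays by an F test over the differences from 0 h, and the 24 h minus 0 h contrast was read from the same fit. Since no combination of line, treatment and time was repeated, the spread behind each p-value is that between time points or between the lines, which includes any change of the response with time. Nothing in the labels says whether separate experiments were pooled or repeated. Only 1 over-expressing line was profiled, so over-expression of IRF9 and other differences between these lines cannot be told apart.

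Before the data were examined, 17 gene lists were fixed, together with the tests, the alternatives and the rule for named genes. The lists hold antiviral effectors, interferon signalling, feedback inhibitors, nucleic acid sensors, class I antigen presentation, interferon-gamma type genes, chemokines and cytokines, NF-kappaB targets, apoptosis, serum immediate-early genes, cell cycle, cholesterol synthesis, amino acid and endoplasmic reticulum stress, hypoxia and glycolysis, hepatocyte functions, markers of other cell types, and housekeeping genes. Of their 377 entries, 344 were measured under a single symbol, and IRF9 is in none. Each list was tested in each comparison with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 255 tests, and again with the correlation estimated from the data. With the estimated correlation 0 of the 255 tests passed, so each list call is followed by that second p. The antiviral effector score is the mean of that list's differences at a time point; its mean was tested by an exact two-sided sign-flip permutation over time points.

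Named genes followed a rule: IRF9 throughout; up to 10 genes with the largest rise and up to 10 with the largest fall among those past the threshold with the same sign at every time compared; up to 4 members of each list with the lowest p; a few signalling genes; and the 5 lowest p where fewer than 5 genes passed. Values are mean log2 differences with ± 1 standard error unless another error is named.

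The control and stimulated arrays of the wild type at 2 h and of the IRF9 line at 8 h ran opposite to all other pairs. Their labels were kept, and each is called the array labelled control or stimulated. As an alternative chosen after seeing this, every comparison was repeated without these pairs, and without 2 h and 8 h in both lines where the lines were compared at matched times. The rule for named genes was then applied again. Because the pairs were recognised by their interferon response, the results without them are not independent evidence that the response exists. A further repeat also left out the wild-type pairs at 8 h and 12 h, which hold the arrays farthest out on the third principal component. Contrasts added after seeing the data were the 24 h minus 0 h count, the early minus late difference between the lines, and the midpoint times of the response.

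Alternatives fixed beforehand were quantile normalization, centring on array medians, a filter on dim genes (third-highest value above the 25th percentile of all values, 3.7228, which left 16486 genes), the mean of all clusters of a gene, robust or untrended eBayes, a threshold of 0.01, other blocks, other phase limits, fry, and leaving out each time point. The fits were tested on simulated data made with known changes. In the design with all arrays, the wild-type response recovered 88.1% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, while the difference between the lines recovered 47.8% and 92.5%. Without the doubted pairs, recovery was 79.1% and 98.5% for the wild-type response, 28.4% and 80.6% for the difference between the lines and 13.4% and 52.2% for that at 1 to 4 h. These simulations held no response that varied over time, which the real data hold.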

Results

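Huh7.5 cells, a human hepatoma line widely used to grow hepatitis C virus, were profiled as the wild type and as a line over-expressing IRF9. IRF9 is the DNA-binding subunit of ISGF3, the transcription factor complex that type I interferon activates to switch on antiviral genes. The study's title concerns IRF9 and the speed of early interferon signalling, so the comparisons are the response to interferon alpha in each line, the difference between these responses, and the lines without stimulation. The 30 arrays comprised 8 control and 7 stimulated time points per line, with no repeated time point, and their medians lay between 5.50 and 5.64 on the log2 scale.

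IRF9 was higher in the over-expressing line on every array. Its log2 level lay between 10.12 and 10.48 on the control arrays of that line, against 6.44 to 7.04 on the wild-type control arrays other than the one labelled control at 2 h. That array stood at 8.59, while its partner labelled stimulated stood at 6.71. The same pair carried the interferon-induced transcripts IFIT1 and MX1 at 9.19 and 8.99 on the array labelled control and at 4.65 and 5.07 on the array labelled stimulated. In the IRF9 line, the array labelled control at 8 h held IFIT1 at 11.28 and MX1 at 11.71, against 5.21 and 6.07 on its partner labelled stimulated. Both pairs therefore ran opposite to the other 12, and every direction below is given with the labels as deposited or without these pairs.

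**Figure D1:**
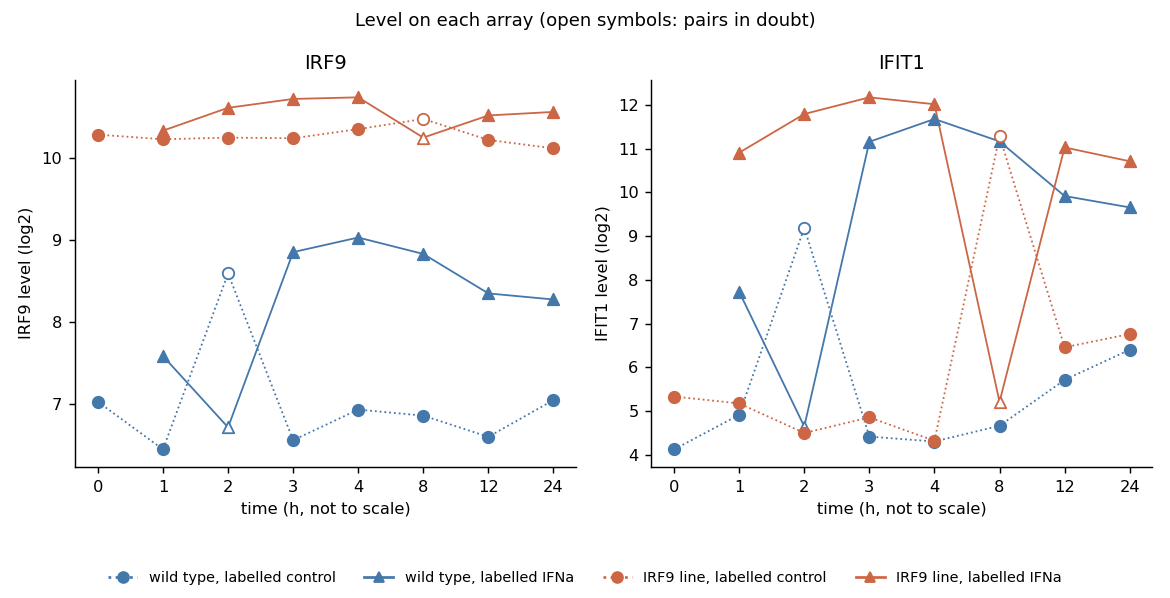
Log2 level of IRF9 (left) and IFIT1 (right) on each of the 30 arrays against time in h, by line and labelled treatment, with 1 array per point. Open symbols mark the wild type at 2 h and the IRF9 line at 8 h, where IFIT1 stood at 9.19 and 11.28 on the arrays labelled control and at 4.65 and 5.21 on those labelled stimulated.

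In wild-type cells, interferon alpha raised a set of antiviral genes, as seen without the doubted 2 h pair. MX1, a GTPase that blocks viral nucleocapsids, rose by 5.39 ± 0.48 (n = 6 time points), IFIT1, which binds viral RNA lacking host cap methylation, by 5.15 ± 0.55, and IFI6 by 4.72 ± 0.57. Of 57 antiviral effectors, 28 rose and 51 did so when adjusted over the list alone, with a mean of 1.62 ± 1.21 (SD over members; camera adjusted p = 1.04e-112; adjusted p = 0.0506 with an estimated correlation). Class I antigen presentation rose in 6 of 14 members, and in 12 adjusted over the list alone (mean 0.79; camera adjusted p = 2.25e-32; adjusted p = 0.0506 with an estimated correlation). B2M, the invariant light chain of class I molecules, rose by 0.82 ± 0.12 and the proteasome activator PSME2 by 0.72 ± 0.11. The endogenous IRF9 transcript itself rose by 1.75 ± 0.11 (adjusted p = 1.4e-07).

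Smaller groups moved through single members in the wild type without the 2 h pair. The RNA sensors IFIH1 and RIGI rose by 3.86 ± 0.60 and 2.47 ± 0.44 among 13 nucleic acid sensors, 3 of which rose adjusted over the list alone (camera adjusted p = 4.99e-06; adjusted p = 0.173 with an estimated correlation). The chemokine CXCL10 rose by 2.15 ± 0.44 and the macrophage growth factor CSF1 by 0.70 ± 0.12 among 18 chemokines and cytokines, with the same 2 adjusted over the list alone (camera adjusted p = 0.0036; adjusted p = 0.252 with an estimated correlation). APOL6 rose by 2.59 ± 0.48 as the single call among 15 interferon-gamma type genes, 5 of which rose adjusted over the list alone (camera adjusted p = 1.06e-09; adjusted p = 0.102 with an estimated correlation). Interferon signalling rose in 1 of 12 members, and in 3 adjusted over the list alone (camera adjusted p = 0.00468; adjusted p = 0.136 with an estimated correlation). NMI, an interferon-induced partner of STAT proteins, rose by 1.37 ± 0.28. Feedback inhibitors had 0 of 14 calls by limma and 1 adjusted over the list alone (camera adjusted p = 0.231), with the ISG15 protease USP18 at 1.40 ± 0.30 (adjusted p = 0.061) and SOCS1, an inhibitor of JAK kinases, at 0.32 ± 0.20.

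With all labels as deposited, limma called 0 genes for the wild-type response, with 721 at an unadjusted p under 0.05; without the 2 h and 8 h pairs it called 54, all higher. Leaving out a further time point gave 31 genes without 3 h, 24 without 4 h, 21 without 8 h and 22 without 12 h, and 7 without the wild-type 8 h and 12 h pairs together. The pairs were left out because of their response, so this test is not independent of it.

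In the IRF9 line, interferon alpha raised genes of the same families, as seen without the doubted 8 h pair. This response keeps 2 h and lacks 8 h, and the wild-type one the reverse. Values and counts of the 2 responses therefore cover unlike times. IFIT1 rose by 6.09 ± 0.55 (n = 6), IFIT2 by 5.61 ± 0.71, IFI6 by 4.98 ± 0.57, MX1 by 4.79 ± 0.48, and RSAD2, which makes a chain-terminating ribonucleotide against viral polymerases, by 3.63 ± 0.59. Of the 57 antiviral effectors 51 rose, 54 adjusted over the list alone, with a mean of 2.08 ± 1.39 (SD over members; camera adjusted p = 3.46e-108; adjusted p = 0.0506 with an estimated correlation). Class I antigen presentation rose in 10 of 14 members, and in 13 adjusted over the list alone (mean 1.04; camera adjusted p = 1.44e-30; adjusted p = 0.0506 with an estimated correlation). IRF9 itself, already high, differed by 0.35 ± 0.11 (adjusted p = 0.21).

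Several further groups held calls in the IRF9 line without the 8 h pair. Interferon-gamma type genes rose in 8 of 15 members, and in 10 adjusted over the list alone (camera adjusted p = 2.33e-17; adjusted p = 0.0506 with an estimated correlation). CD274, the checkpoint ligand PD-L1, rose by 3.15 ± 0.55. The apoptosis list rose in 5 of 16 members, and in 10 adjusted over the list alone (camera adjusted p = 2.9e-10; adjusted p = 0.0506 with an estimated correlation). The BH3-only protein PMAIP1 stood at 0.85 ± 0.14 and the inflammatory caspase CASP4 at 0.55 ± 0.09. Chemokines and cytokines rose in 4 of 18 members, and in 6 adjusted over the list alone (camera adjusted p = 7.83e-06; adjusted p = 0.121 with an estimated correlation). CXCL10 stood at 3.71 ± 0.44 and the death ligand TNFSF10 at 3.20 ± 0.51. Nucleic acid sensors rose in 5 of 13, and in 6 adjusted over the list alone (camera adjusted p = 6.04e-10; adjusted p = 0.0936 with an estimated correlation). Interferon signalling genes rose in 4 of 12, the same number adjusted over the list alone (camera adjusted p = 4.85e-05; adjusted p = 0.0573 with an estimated correlation), IRF1 by 2.30 ± 0.46. Both feedback inhibitors that passed rose, USP18 by 2.37 ± 0.30 and SOCS1 by 1.01 ± 0.20, while the list of 14, with 2 adjusted over the list alone, did not pass (camera adjusted p = 0.0891).

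Markers of other cell types were not called as a list in the IRF9 line (camera adjusted p = 0.121), yet the lysosomal glycoprotein CD68 rose by 0.97 ± 0.14 and smooth muscle actin ACTA2 by 0.73 ± 0.12, the same 2 adjusted over the list alone. Cell cycle genes had 0 calls of 31 by limma, 2 lower adjusted over the list alone, and a mean of -0.09 (camera adjusted p = 2.45e-06; adjusted p = 0.324 with an estimated correlation). Housekeeping genes had 1 lower call, the cyclophilin PPIA at -0.22 ± 0.05, also adjusted over the list alone (camera adjusted p = 0.0201; adjusted p = 0.33 with an estimated correlation). NF-kappaB targets had 1 higher call, SOD2 at 0.39 ± 0.07, and 2 adjusted over the list alone (camera adjusted p = 0.0251; adjusted p = 0.595 with an estimated correlation). The largest falls were small, with TUBB8 at -0.40 ± 0.09, DNAAF2 at -0.34 ± 0.08 and the fructose kinase KHK at -0.32 ± 0.08.

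As labelled, limma called 0 genes for the response of the IRF9 line, with 1139 at an unadjusted p under 0.05; without the doubted pairs it called 277, of which 265 were higher and 12 lower. The count fell to 156 without 2 h, 122 without 3 h and 150 without 4 h. Of the 54 genes higher in the wild type, 52 were also among the 265 higher in the IRF9 line, against 0.777 for independent lists (Fisher's exact p = 1.16e-95). The lines shared no control arrays, but both lists came from 1 fit with a shared variance estimate. Pairs had also been left out for their response, and genes that respond together are not independent. The p therefore does not measure chance.

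Averaged over both lines without the doubted pairs, the response spread from a few genes to many. At 1 h limma called 6 genes, all higher: IFIT1 by 4.27 ± 0.41, the transcription factor IRF1 by 3.75 ± 0.18, MX1 by 2.18 ± 0.22, TRIM21 by 1.68 ± 0.22, ZNFX1 by 1.53 ± 0.23 and JUNB by 0.78 ± 0.11. The calls numbered 69 at 2 h, 131 at 3 h, 136 at 4 h, 95 at 8 h, 96 at 12 h and 98 at 24 h. Antiviral effectors called among the 57 went from 3 at 1 h to 43 at 4 h and 24 at 24 h, and adjusted over the list alone from 17 to 56 and 36. At 4 h the camera adjusted p was 2.74e-161 and the adjusted p = 0.0506 with an estimated correlation. MX1 and IFI6 stayed high, at 5.03 ± 0.22 and 6.15 ± 0.33 at 24 h. IRF1 was high early: on wild-type arrays it stood at 9.38, 8.94 and 8.76 at 1, 3 and 4 h of stimulation and at 6.14, 5.99 and 5.77 at 8, 12 and 24 h.

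Genes lower in stimulated cells at 3 h included the growth factor TGFB2 at -0.61 ± 0.13 and the Notch ligand JAG1 at -0.44 ± 0.08. At 12 h the decoy receptor TNFRSF10D stood at -1.46 ± 0.15 and the polyamine enzyme ODC1 at -0.66 ± 0.07. As labelled, limma called 0 genes at 1, 2, 3, 4, 8 and 12 h, with 374, 664, 1532, 1084, 1783 and 1061 at an unadjusted p under 0.05, and 3 at 24 h, namely SLC6A14, KRT23 and BCS1L (adjusted p = 0.0453). The 374 and 664 lie under the 0.05 share of genes expected by chance. The 24 h count was 0 with centred arrays or without a trend, 16 with quantile normalization and 24 with robust eBayes. Each time point rests on 2 lines, and on a single line at 2 h and 8 h without the doubted pairs, where the lone line is assumed to vary like the others. At 12 h the count was 52 without the wild-type 8 h and 12 h pairs. The 8 h count rests on that wild-type 8 h pair alone, so no such repeat was possible there.

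The early response was larger in the IRF9 line. The mean of the 57 antiviral effectors reached 0.98 at 1 h, 2.16 at 2 h, 2.84 at 3 h and 3.05 at 4 h in that line, against 0.27 at 1 h, 1.56 at 3 h and 2.42 at 4 h in the wild type. The IRF9 line minus the wild type was 0.63 at 4 h, 0.20 at 12 h and 0.32 at 24 h. At 1 h, 18 effectors exceeded 1 on the log2 scale in the IRF9 line and 4 in the wild type. The doubted pairs gave -0.73 at 2 h in the wild type and -2.60 at 8 h in the IRF9 line.

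**Figure D2:**
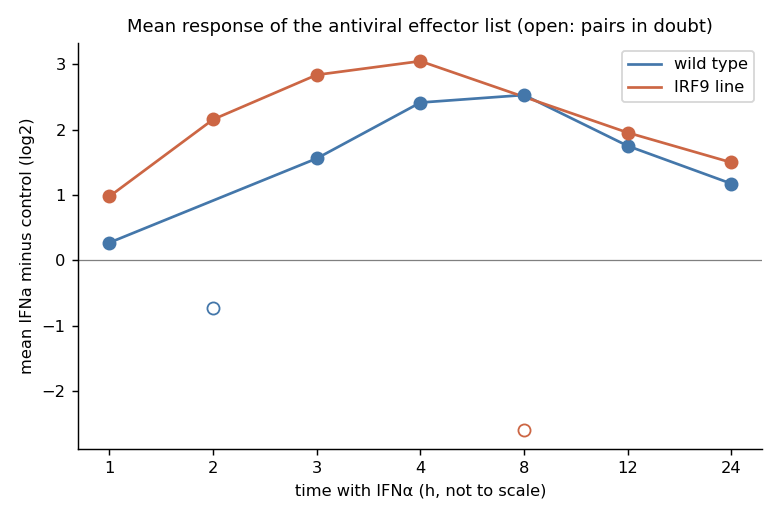
Mean log2 difference between arrays labelled stimulated and control over 57 antiviral effectors against time in h, 1 value per line and time point; lines join the time points kept and open symbols mark the doubted pairs. The IRF9 line lies above the wild type at 1 h (0.98 and 0.27), 3 h (2.84 and 1.56) and 4 h (3.05 and 2.42).

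Single genes showed this difference at 1, 3 and 4 h, without the doubted times. The response of IFIT2 was larger in the IRF9 line by 3.74 ± 0.59, of TNFSF10 by 3.01 ± 0.23, of RSAD2 by 3.01 ± 0.30, of CD274 by 2.53 ± 0.35 and of CXCL10 by 2.43 ± 0.20, each in 3 of 3 time points. IFIT2 had risen by 6.55 at 1 h in the IRF9 line and stood at -0.07 in the wild type. Of 57 antiviral effectors, 16 had a larger early response in the IRF9 line and 0 a smaller one, or 43 and 1 adjusted over the list alone, at a mean of 0.87 ± 0.76, SD over members (camera adjusted p = 2.83e-73; adjusted p = 0.102 with an estimated correlation). IRF9 had a smaller log2 response in its over-expressing line, by -1.52 ± 0.15. The lines started from unlike levels: at 3 h IRF9 stood at 10.24 on the control and 10.72 on the stimulated array of that line. In the wild type it stood at 6.55 and 8.85. A smaller log2 change from a higher level need not be a smaller absolute rise.

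Other groups also differed early without the doubted times. Class I antigen presentation had 3 larger responses of 14, and 8 adjusted over the list alone (camera adjusted p = 2.2e-19; adjusted p = 0.144 with an estimated correlation). The peptide transporter TAP1 differed by 1.30 ± 0.20. Nucleic acid sensors had 3 of 13, and 4 adjusted over the list alone (camera adjusted p = 3.08e-08; adjusted p = 0.173 with an estimated correlation). IFIH1 differed by 1.83 ± 0.27 and the adaptor MYD88 by 1.21 ± 0.16. Chemokines and cytokines had 3 of 18, the same number adjusted over the list alone (camera adjusted p = 3.52e-06; adjusted p = 0.297 with an estimated correlation). Interferon-gamma type genes had 2 of 15, and 4 adjusted over the list alone (camera adjusted p = 5.42e-08; adjusted p = 0.304 with an estimated correlation). The feedback inhibitor USP18 differed by 1.45 ± 0.14, SOCS1 by 0.82 ± 0.23 (adjusted p = 0.35) and IRF1 by -0.30 ± 0.20 (adjusted p = 1).

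**Figure D3:**
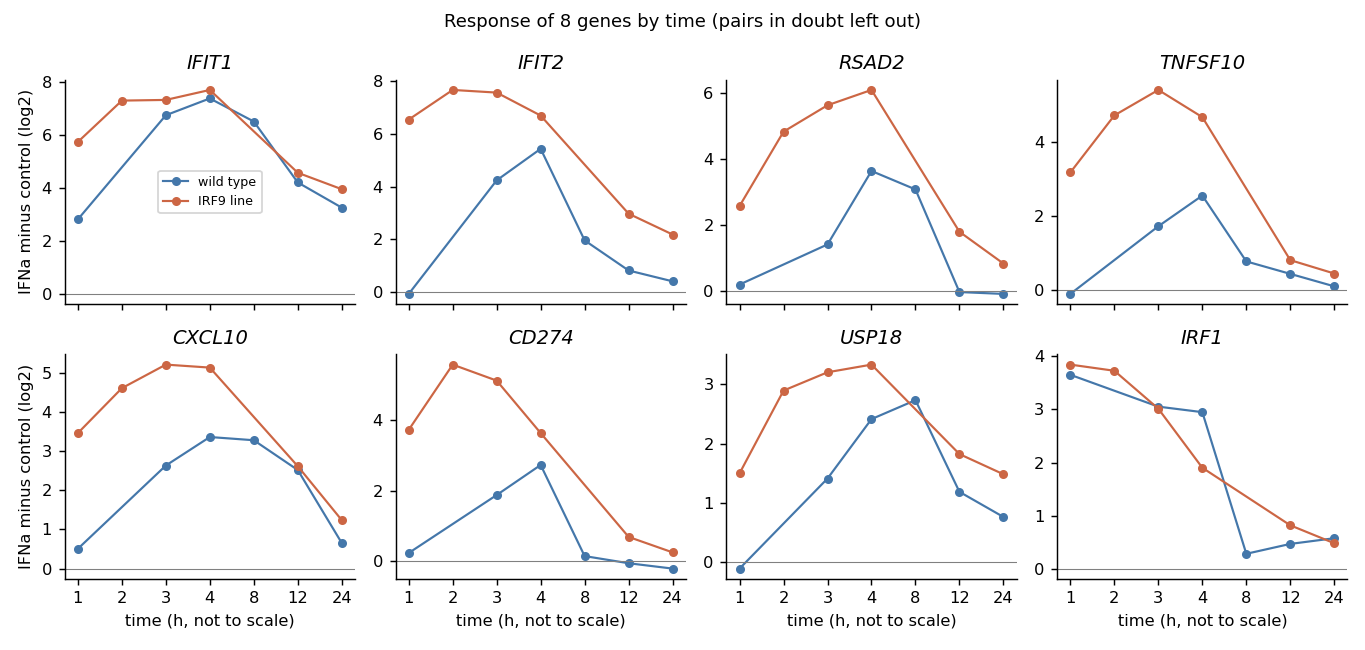
Log2 difference between stimulated and control arrays of 8 genes against time in h in both lines, 1 value per line and time point, without the doubted pairs. IFIT2 stands at 6.55 in the IRF9 line and -0.07 in the wild type at 1 h, while IRF1 stands at 3.85 and 3.65.

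For 1 to 4 h limma called 62 genes without the doubted times, of which 60 had a larger response in the IRF9 line, and 3 as labelled: FAM111A at 0.84 ± 0.10, LIMA1 at 0.66 ± 0.08 and the pseudogene ADCY10P1 at -1.07 ± 0.13. The count of 3 was 0 without 2 h, 3 h or 24 h, with centred arrays or without a trend, 6 without 1 h and 96 without 8 h. The 62 became 148 without 1 h, 19 without 3 h and 37 without 4 h. The score's early difference was 0.87 ± 0.35 (SD, n = 3) without 2 h, where the exact p of 0.25 is the smallest possible, and 1.38 ± 1.05 (SD, n = 4) as labelled, exact p = 0.125, again the smallest possible.

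Over the whole course as labelled, the score averaged 1.28 ± 1.17 in the wild type (SD, n = 7, exact p = 0.0469, adjusted 0.208) and 1.41 ± 1.91 in the IRF9 line (exact p = 0.109). The difference between the lines was 0.13 ± 2.49 (exact p = 0.906). Without the doubted pairs the score averaged 1.62 ± 0.84 and 2.08 ± 0.79 (SD, n = 6), each with an exact p of 0.0313, the smallest possible, and an adjusted p of 0.0781 that does not pass. Every kept pair was positive because the negative ones had been left out. The wild type lacked 2 h and the IRF9 line 8 h, so these 2 means cover unlike times. Over the times kept in both lines the difference was 0.63 ± 0.42 (SD), positive at 5 of 5 time points. Its exact p of 0.0625 is the smallest possible.

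For 8 to 24 h limma called 0 genes, with 598 at an unadjusted p under 0.05 without the doubted times and 493 as labelled. Both counts lie under the 0.05 share of genes expected by chance. The antiviral effectors had a mean difference of 0.26 without 8 h, with 5 larger and 5 smaller responses adjusted over the list alone (camera adjusted p = 0.0657), and of -1.54 as labelled (camera adjusted p = 5.51e-29; adjusted p = 0.634 with an estimated correlation), with 0 called adjusted over the list alone. Over the whole course limma called 12 genes without the doubted times and 0 as labelled, with 497 at an unadjusted p under 0.05, again under that share. The 12 included IFI44L at 2.44 ± 0.41, IFIT3 at 2.04 ± 0.30, XAF1 at 1.40 ± 0.21, the ectoenzyme CD38 at 1.19 ± 0.16 and IRF9 at -1.36 ± 0.12. For IRF9 the lines again started from unlike levels. The count of 12 became 52 without 1 h, 7 without 3 h, 6 without 4 h, 62 without 12 h and 6 without 24 h.

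The early difference minus the late one, added after the data were seen, gave 0 genes by limma as labelled, with 822 at an unadjusted p under 0.05. That count lies under the 0.05 share of genes expected by chance. The antiviral effectors then had a mean of 2.91 (camera adjusted p = 1.49e-44; adjusted p = 0.324 with an estimated correlation). It gave 1 gene without the doubted times and a mean of 0.61 for the antiviral effectors (camera adjusted p = 1.57e-29; adjusted p = 0.511 with an estimated correlation). Among 44 effectors that exceeded 1 in both lines, the response crossed its midpoint at a median of 2.64 h in the wild type and 1.81 h in the IRF9 line, and earlier in the IRF9 line for 43 of them. These times were interpolated linearly without 2 h and 8 h in both lines, so both medians fall in the gap from 1 to 3 h. The 2 h pair of the IRF9 line was left out with them. Using it in that line alone gave a median of 1.62 h, but an added point on a rising curve can move an interpolated time by construction, so this does not bear on the difference. Genes are not independent replicates, so no test was run on these times.

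Without stimulation, the IRF9 line differed from the wild type in a modest set of genes besides IRF9, which was higher by 3.27 ± 0.18 (n = 8 time points). The 8 time points include 2 h and 8 h, and so the doubted arrays labelled control. At 2 h IRF9 stood at 8.59 on the doubted wild-type array and at 10.25 in the IRF9 line. That gap is smaller than at the other times and lowers the mean. The aminopeptidase ERAP1, which trims peptides for class I molecules, was higher by 1.15 ± 0.11, the protease inhibitor A2M by 1.03 ± 0.04, the neuropeptide galanin (GAL) by 0.87 ± 0.05 and THBS4 by 0.81 ± 0.05. Lower genes included ANXA1 at -1.10 ± 0.11, the protease CTSE at -0.93 ± 0.05, sucrase-isomaltase (SI) at -0.78 ± 0.07, the oxidase NOX1 at -0.67 ± 0.08 and the glucose transporter SLC2A2 at -0.65 ± 0.08. Each kept its sign at 8 of 8 time points.

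Immediate-early genes were higher in 3 of 22 members, and in 7 adjusted over the list alone (camera adjusted p = 9.2e-10; adjusted p = 0.587 with an estimated correlation): EGR1 by 0.50 ± 0.07, DUSP6 by 0.29 ± 0.04 and IER3 by 0.34 ± 0.06. Antiviral effectors had 0 calls by limma as labelled, and 0 adjusted over the list alone, with a mean of 0.35 (camera adjusted p = 7.8e-09; adjusted p = 0.732 with an estimated correlation). Without the doubted times the mean was 0.11, with 5 higher and 13 higher adjusted over the list alone (camera adjusted p = 1.24e-05; adjusted p = 0.0573 with an estimated correlation). The ubiquitin ligase DTX3L was higher by 1.11 ± 0.10, IFIT5 by 0.75 ± 0.12 and MX1 by 0.68 ± 0.09. Hypoxia and glycolysis genes had 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.000341; adjusted p = 0.587 with an estimated correlation), and the single gene called, NDRG1, was lower, at -0.20 ± 0.04. Of the cell type markers, lysozyme (LYZ) was higher by 0.33 ± 0.05 and PECAM1 was at -0.39 ± 0.09, the same 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.945).

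Under interferon alpha the same contrast gave IRF9 at 2.30 ± 0.22 (n = 7), A2M at 1.01 ± 0.04, ANXA1 at -1.16 ± 0.06, CTSE at -0.68 ± 0.07 and the adhesion molecule EPCAM at -0.63 ± 0.08. The 7 time points include both doubted times, and at 2 h the wild-type array labelled stimulated held IRF9 at 6.71. Genes called on control arrays that did not pass here include NOX1 at -0.36 ± 0.10 (adjusted p = 0.132), EGR1 at 0.33 ± 0.08 (adjusted p = 0.0716) and IER3 at 0.18 ± 0.06 (adjusted p = 0.259). DTX3L, at 0.45 ± 0.42 (adjusted p = 0.731), and IFIT5, at 1.33 ± 0.53 (adjusted p = 0.305), did not pass either. These 2 were called on control arrays only without the doubted times, while the values here include those times. The 2 contrasts therefore use unlike arrays for these genes and do not show that their difference is lost under interferon. Antiviral effectors called between the lines under interferon numbered 0 as labelled by limma, with 0 adjusted over the list alone (camera adjusted p = 4.01e-06; adjusted p = 0.787 with an estimated correlation). Without the doubted times they numbered 23, with 44 adjusted over the list alone (camera adjusted p = 5.01e-43; adjusted p = 0.163 with an estimated correlation).

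**Figure D4:**
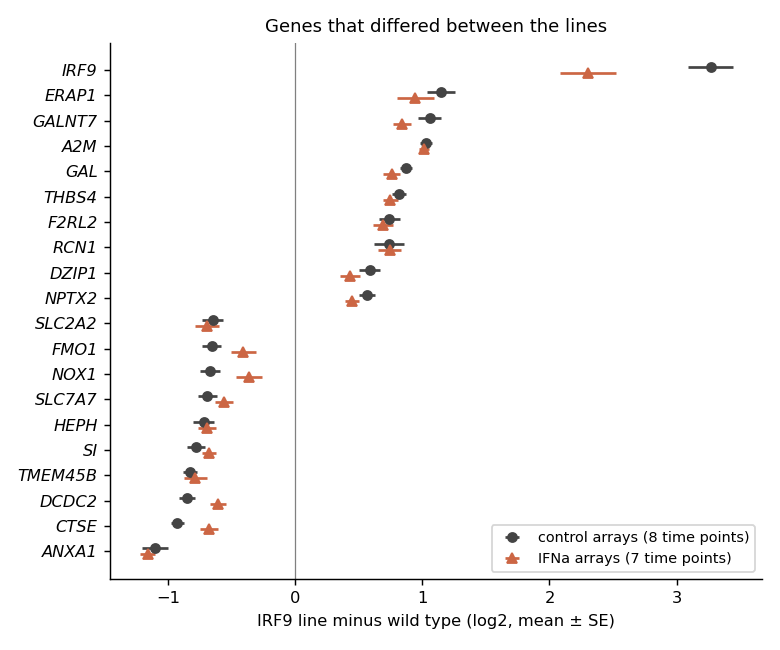
Mean log2 difference between the IRF9 line and the wild type, with its standard error, for the genes with the largest differences on the control arrays, shown for 8 control and 7 stimulated time points with all labels as deposited. IRF9 lies at 3.27 and 2.30, and ANXA1 at -1.10 and -1.16.

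On the control arrays limma called 264 genes between the lines, 95 higher and 169 lower in the IRF9 line, and 114 without the doubted times, 53 higher and 61 lower. The 114 became 37 without 0 h, 181 without 1 h, 34 without 3 h, 42 without 4 h and 51 without 24 h. The 264 became 155 without 0 h, 152 without 2 h, 155 without 3 h, 133 without 4 h and 427 without 12 h, and 131 with arrays centred on their medians. Only 1 over-expressing line was profiled, so effects of IRF9 and other differences between the lines are confounded. On the stimulated arrays it called 248, 134 higher and 114 lower, and 222 without the doubted times. Leaving out single times gave 115 without 1 h, 117 without 2 h, 147 without 3 h, 136 without 4 h, 436 without 8 h, 113 without 12 h and 164 without 24 h. The 222 became 110 without 1 h, 114 without 3 h and 98 without 4 h.

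Unstimulated cells changed in many genes over the 24 h course. Comparing 24 h with 0 h over both lines, TXNIP, a thioredoxin inhibitor regulated by glucose supply, rose by 2.87 ± 0.14 and the aldo-keto reductase AKR1C1 by 1.54 ± 0.12. The metallothionein MT1X fell by 3.07 ± 0.11, the immediate-early factor EGR1 by 2.54 ± 0.15 and the aryl hydrocarbon receptor target CYP1A1 by 2.28 ± 0.26. Cholesterol synthesis rose in 12 of 18 members and fell in 1, or 13 and 1 adjusted over the list alone (mean 0.41; camera adjusted p = 1.21e-09; adjusted p = 0.587 with an estimated correlation). FDPS, which makes farnesyl diphosphate, stood at 0.90 ± 0.08 and lanosterol synthase (LSS) at 0.81 ± 0.07. Immediate-early genes fell in 12 of 22, and in 15 adjusted over the list alone (mean -0.58; camera adjusted p = 8.16e-09; adjusted p = 0.587 with an estimated correlation). MYC stood at -1.20 ± 0.08 and JUN at -1.44 ± 0.13. NF-kappaB targets fell in 7 of 17, and in 8 adjusted over the list alone (mean -0.59; camera adjusted p = 9.93e-05; adjusted p = 0.664 with an estimated correlation). The chemokine CCL20 stood at -1.93 ± 0.15, CXCL8 at -1.85 ± 0.25 and CXCL1 at -1.84 ± 0.23.

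Some proliferation, stress and liver genes were also lower at 24 h, while these lists did not pass with an estimated correlation. Cell cycle genes fell in 9 of 31, the same number adjusted over the list alone (mean -0.21; camera adjusted p = 0.000153; adjusted p = 0.688 with an estimated correlation). The replication helicase subunit MCM5 stood at -0.65 ± 0.08 and the kinetochore protein CENPF at -0.95 ± 0.10. Amino acid and endoplasmic reticulum stress genes fell in 7 of 20 and rose in 1, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.0058; adjusted p = 0.664 with an estimated correlation). The amino acid transporter SLC7A5 stood at -1.19 ± 0.09. Hepatocyte functions fell in 9 of 30, with 9 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00694; adjusted p = 0.66 with an estimated correlation). The fibrinogen chain FGB stood at -1.73 ± 0.06 and FGA at -0.97 ± 0.08. The kinase JAK1, which transmits the interferon signal, fell by 0.67 ± 0.06. Housekeeping genes were not called as a list (camera adjusted p = 0.999), with the transferrin receptor TFRC at 1.30 ± 0.09 and POLR2A at -0.63 ± 0.09; adjusted over the list alone 2 were higher and 2 lower.

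**Figure D5:**
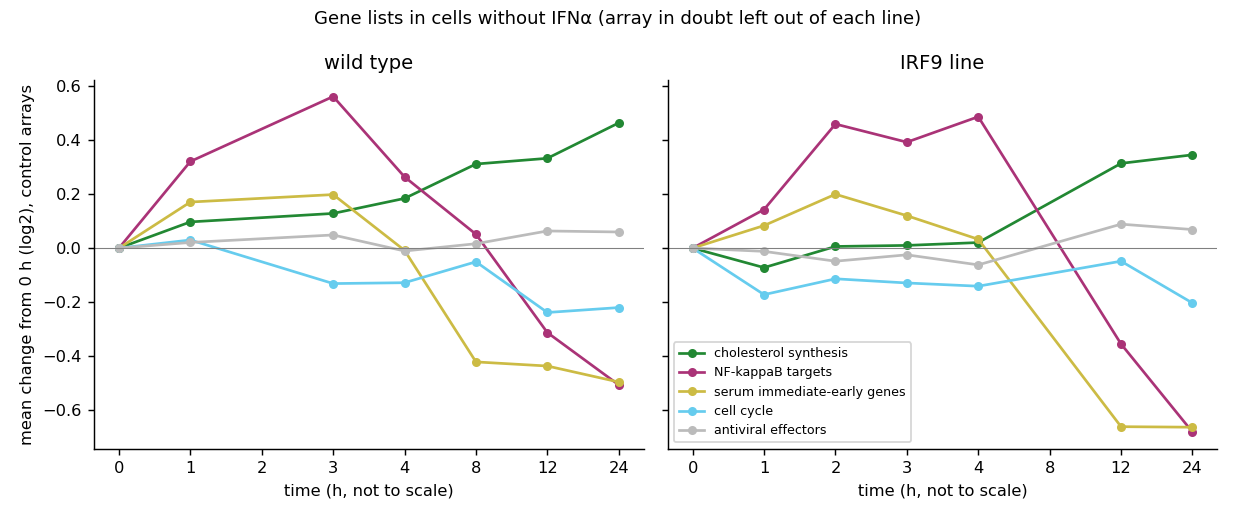
Mean log2 change from 0 h of 5 gene lists on the control arrays against time in h, by line, 1 array per point, without the doubted array of each line. Cholesterol synthesis reaches 0.46 and 0.35 at 24 h in the wild type and the IRF9 line, and NF-kappaB targets reach -0.51 and -0.68.

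The F test over all times called 3333 genes, and the 24 h minus 0 h contrast 3180, of which 1242 rose and 1938 fell. Without the doubted arrays the F test called 2554 and the contrast 2949. The F test over all arrays includes the doubted arrays labelled control at 2 h and 8 h, so its count is not change in unstimulated cells alone. The lines served as the 2 samples at each time point.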

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

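The tests of the 2 pairs that ran opposite to the others, of the early difference between the lines and of the line differences without interferon were chosen only after those results were seen, as was every repeat without the doubted pairs.

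Antiviral genes ran opposite to the labels in the IRF9 line at 8 h. The mean of the antiviral effectors between the arrays labelled stimulated and control was -2.60, far from the other 6 time points. Between the lines at 8 h it was 2.76 on arrays labelled control and -2.37 on arrays labelled stimulated. Class I antigen presentation stood apart in the same 3 ways at 8 h, at -1.51, 1.68 and -1.17. On the arrays labelled control at 8 h, the IRF9 line was also far above the wild type in nucleic acid sensors (0.90), interferon-gamma type genes (0.83), chemokines and cytokines (0.56) and apoptosis genes (0.30).

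At 2 h the wild type stood apart. Its IRF9 level on the array labelled control was 8.59, and its feedback inhibitors differed by -0.11 between the labelled treatments. Interferon signalling genes differed by 0.74 between the lines on arrays labelled stimulated at 2 h. Hepatocyte functions stood apart at 24 h, at 0.10 for the response of the IRF9 line and -0.0934 between the lines' control arrays. Of 72 groups of values tested for a sample far from the rest, 15 had one, against 3.6 expected by chance if the groups were independent. They are not, since they share arrays. All flagged groups other than hepatocyte functions fall at the times of the doubted pairs, so they are not separate events.

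With all labels as deposited, the lines' responses differed at 1 to 4 h for ADCY10P1 (-1.07), FAM111A (0.84) and LIMA1 (0.66) by limma. The count of these genes was 0 without 2 h, 3 h or 24 h or with centred arrays, 6 without 1 h and 96 without 8 h. By camera at the preset correlation they also differed at 1 to 4 h for antiviral effectors (1.38), interferon signalling (0.36), nucleic acid sensors (0.70), class I antigen presentation (0.67), interferon-gamma type genes (0.79), chemokines and cytokines (0.58) and apoptosis (0.29). At 8 to 24 h the differences were -1.54 for antiviral effectors, -0.83 for class I antigen presentation, -0.31 for interferon-gamma type genes, -0.24 for chemokines and cytokines, -0.22 for NF-kappaB targets and 0.14 for amino acid and endoplasmic reticulum stress. Over the whole course NF-kappaB targets differed by -0.0839 and apoptosis by 0.13. With an estimated correlation, 0 list tests passed, and these values include the doubted pairs.

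Transcript clusters without a single gene symbol, 13837 in number, were tested apart for the interferon response. As labelled, 1 was called in the wild type, lower, and limma called 0 in the IRF9 line, with 847 at an unadjusted p under 0.05. Without the doubted pairs, 1 was called in the wild type and 29 in the IRF9 line, of which 28 were higher, with a largest difference of 2.68.

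The 2 opposite pairs may carry each other's labels, which stays open. Their correlations with the remaining pairs across antiviral effectors, -0.823 and -0.867, restate how the pairs were recognised and add no evidence for an exchange. The arrays labelled control stood at mean antiviral effector levels of 6.23 (wild type) and 8.24 (IRF9 line). The other stimulated arrays of these lines spanned 5.76 to 8.01 and 6.57 to 8.59. An exchange would give such levels, but the labels cannot be checked from the arrays alone. Interferon or stimulated RNA reaching the control array alone is argued against: the arrays labelled stimulated lay at most -0.0278 from the highest other control, so they lacked the response. An exchange with the other line is argued against, since 4 of the 4 arrays lay on the side of their own line over 100 genes. No biological explanation was tested.

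The larger early response of the IRF9 line at 1, 3 and 4 h may come from IRF9 itself. Lower control levels would raise a difference, but antiviral effectors were higher in the control arrays of that line by 0.0821 ± 0.0203 (SD, n = 3). No large shift of whole arrays was seen, with a median of -0.0176 over all genes tested and quartiles of -0.101 and 0.0757. This was in part fixed beforehand, since the array medians already lay between 5.50 and 5.64. Only 1 over-expressing line was profiled, so other differences between the lines remain open and untested.

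The line differences without interferon, 114 genes without the doubted times (37 without 0 h, 181 without 1 h, 34 without 3 h, 42 without 4 h and 51 without 24 h), may in part reflect unstimulated interferon signalling. Of these genes, 14 (12.3%) also changed with interferon, 10 of 53 higher and 4 of 61 lower in the IRF9 line, against 1.73 for independent lists, although both tests share control arrays. The remaining genes were not called for a response to interferon. Those calls varied with the time points kept (21 to 70 in the wild type). A missing call therefore does not exclude interferon signalling as the whole cause. Noise of single control arrays is argued against, since 110 (96.5%) had the same sign on the stimulated arrays. Over-expression of IRF9 and clonal or handling differences of the line stay open.

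Labels were exchanged within time-matched pairs as a measure of chance. As labelled, the real count was 0 for the wild-type response, the response of the IRF9 line and the difference between the lines. All 64 of 64 splits reach such a count, so this says nothing about chance. The highest other counts were 2, 352 and 10, and the 352, with the labels of the IRF9 line at 8 h exchanged, point to a structure of the samples at that time. The splits were too few for a share under 0.05 at 1 to 4 h (1 of 8 splits, real 3, highest other 0) and at 8 to 24 h (4 of 4, real 0, highest other 0).

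For the lines on control arrays, 1 of 100 splits, the real one, called 264 and the highest other 3. On stimulated arrays, 1 of 64 called 248 and the highest other 70. These splits argue against noise of single arrays as the source. They cannot address a chance difference between the lines, since serial arrays of 1 line are not independent cultures. Without single times the 264 became 155 (0 h), 152 (2 h), 155 (3 h), 133 (4 h) and 427 (12 h). The 248 became 115 (1 h), 117 (2 h), 147 (3 h), 136 (4 h), 436 (8 h), 113 (12 h) and 164 (24 h).

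Without the doubted pairs, the splits for the lines on control arrays again argue only against noise of single arrays (1 of 32 splits, real 114, highest other 1). There the count was 37 without 0 h, 181 without 1 h, 34 without 3 h, 42 without 4 h and 51 without 24 h. For the responses of the wild type (real 54, highest other 29) and the IRF9 line (real 277, highest other 32), the pairs had been kept for their direction, so the splits do not measure chance. The splits were too few for the difference between the lines (real 12, highest other 11), for that at 1 to 4 h (real 62, highest other 0) and for the lines on stimulated arrays (real 222, highest other 1).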

How the results depend on the processing

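The repeats without the doubted pairs, and those also without the wild-type 8 h and 12 h pairs, were chosen after the data were seen. Where no cause is given, the cause was not tested.

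The interferon responses depended on the doubted pairs. Without them, and then also without the wild-type 8 h and 12 h pairs, limma called 54 and 7 genes in the wild type, 277 and 307 in the IRF9 line, 12 and 62 for the difference between the lines, and 62 and 53 for that at 1 to 4 h. By time the counts were 6 and 8 at 1 h, 69 and 71 at 2 h, 131 and 141 at 3 h, 136 and 137 at 4 h, 96 and 52 at 12 h and 98 and 104 at 24 h, and 95 at 8 h without the doubted pairs. Separate effects for 1 to 4 h and 8 to 24 h gave 38 in the IRF9 line.

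With the labels as deposited, leaving out each time point in turn gave 0 to 1 genes for the wild type, 0 to 296 for the IRF9 line (296 without 8 h), 0 to 13 for the difference between the lines (13 without 8 h), 0 to 96 for that at 1 to 4 h (96 without 8 h) and 0 to 0 at 8 to 24 h, where 493 genes had an unadjusted p under 0.05 by limma. Without the doubted pairs it gave 21 to 70 for the wild type and 122 to 304 for the IRF9 line. The 3 genes at 1 to 4 h became 0 with arrays centred on their medians, without a trend or at a threshold of 0.01, 6 with robust eBayes and 5 at 1 to 3 h. The 3 genes at 24 h became 16 with quantile normalization, 24 with robust eBayes, and 0 with centred arrays, without a trend or at 0.01.

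Between the lines on control arrays, 264 genes became 131 with centred arrays, 150 without a trend, 106 at 0.01, 55 without a time block, 114 without the doubted times, 152 also without the pairs at 8 h and 12 h, and 133 to 427 without single times (133 without 4 h, 427 without 12 h). On stimulated arrays, 248 became 123 without a trend, 73 at 0.01, 38 without a time block, 165 without the doubted and the 8 h and 12 h pairs, and 113 to 436 without single times (113 without 12 h, 436 without 8 h). A stricter threshold calls fewer genes by construction. The time course of control arrays gave 2198 calls with centred arrays, 2006 at 0.01 and 2958 to 4237 without single times. Its 24 h contrast gave 1859 at 0.01 and 2847 to 3894 without single times.

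Of the list tests, 0 passed with an estimated correlation, with or without the doubted pairs, and fry called 4 by direction and 29 mixed. The antiviral score of the IRF9 line was 2.08 without the doubted pair. Its mean difference between the lines, 0.13 as labelled, was 0.63 without the doubted times and was reversed to -0.33 without 2 h and to -0.06 without 3 h, and at 8 to 24 h it was reversed to 0.26 without the doubted 8 h. Leaving out single times gave 1.07 to 1.62 for the wild type, 1.14 to 2.08 for the IRF9 line, -0.33 to 1.01 for their difference, 0.87 to 1.63 at 1 to 4 h and -2.47 to 0.26 at 8 to 24 h. A score over effectors past the threshold in both lines had 0 members as labelled by limma and gave no value.

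Of 1174 values of named genes under the alternatives, 1113 kept their direction and side of the threshold, 40 no longer passed, 21 newly passed and 0 reversed. A value that did not pass also counts as kept when it fails again. The tally does not carry over to the interferon responses without the doubted pairs. There the calls by limma went from 0 to 54 in the wild type and from 0 to 277 in the IRF9 line. IRF9 at 2 h stood at -0.76 as labelled over both lines and at 0.36 in the IRF9 line, the only line then kept. Signal over background limits what an array shows for dim genes, and no background measure was used here.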

Other observations

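The tests below without the doubted pairs, and the histone genes named, were chosen only after the data were seen.

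Single histone genes differed both ways in interferon-treated cells at 24 h, and histones as a group were not tested. Averaged over both lines at 24 h, H4C3 stood at -0.64 ± 0.07 (adjusted p = 0.000411 by limma, lower in 2 of 2 lines), H1-1 at -0.53 ± 0.09 (adjusted p = 0.013) and H1-5 at -0.38 ± 0.08 (adjusted p = 0.0415), while H2AC25 stood at 0.92, H2BC14 at 0.74 and H2BC26 at 0.85. With all labels as deposited, limma called none of these histone genes at 24 h (H4C3 adjusted p = 0.242). At 12 h H4C3 stood at -0.65 ± 0.07.

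The decoy receptor TNFRSF10D, which binds the death ligand TNFSF10 without passing on a full signal, stood at -2.11 at 8 h. Only the wild-type 8 h pair was used there, and it holds an array far out on the third principal component. IRF1 and SOCS1 responded early in the IRF9 line, at 3.85 and 1.85 at 1 h, and stood at 0.48 and 0.07 at 24 h.

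In unstimulated cells without the doubted arrays, IFIT1 rose by 1.85 ± 0.23 from 0 h to 24 h, while CXCL10 stood at -1.89 ± 0.23. With all labels as deposited, the antiviral effectors were not called over that time, at a mean of 0.06 (camera adjusted p = 0.811).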
